A study of Rattus norvegicus with 18 samples.

How the data were processed

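The series holds 18 arrays of rat cortical astrocytes, 6 controls and 3 at each of 12 hours, 1 day, 3 days and 5 days on the beta-amyloid peptide of residues 25 to 35. The deposited table gives 1 linear intensity (signal) per probe set and array for 1322 probe sets. The software, its version and the scaling target are not given in the sources used here. From the values, the mean without the lowest and highest 2% of values was 502.067 to 502.632 on every array, so the deposited intensity was already scaled between arrays and was not scaled again. No column gave detection calls. At most 0.713% of values were identical between any 2 arrays.

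The test, the scaling rule, the floor, the filter, the gene lists and the rule for named genes were chosen before the data were examined. Values under the 10th percentile of the table, a signal of 11.3, were set to it, and log2 was taken. The 59 control probe sets were left out. Of the other 1263, those above the 30th percentile, a signal of 44.9, on at least 3 of the 18 arrays were kept, which left 1027. Fold changes of genes near the floor are understated. Where all arrays of a group were at the floor, the fold is a bound, the mean log2 value of the other group against the floor, and is written as at least that size.

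Gene symbols came from the platform annotation that pairs probe sets with genes. Among the 1263 probe sets, 1137 had 1 symbol, 8 had several and 118 had none, and those with several or none were tested and counted but not named. Of the single-symbol probe sets, 1132 matched the reference gene table by gene identifier, and 0 symbols changed. Probe sets of a gene were not averaged.

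All 18 arrays were fitted in 1 model with 5 groups in limma 3.58.1 on R 4.3.3 (lmFit and eBayes without trend or robust options), with 13 residual degrees of freedom and a median residual SD of 0.490. The contrasts were each exposure time against control, the mean of the 4 times against control, consecutive times, 5 days against 12 hours, and the slope of log2 signal on log2 hours over the 4 times. A moderated F-test covered the 5 groups. All limma tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison with a threshold of 0.05. Folds are differences of mean log2 values.

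Of 24 gene lists of astrocyte, inflammation, stress, signalling, receptor, channel and cell type genes, with 732 genes, 258 genes were measured. The 19 lists with at least 5 measured genes were tested with camera at its preset correlation of 0.01, and with an estimated correlation and fry as alternatives, taking for each gene the probe set with the highest mean. The untested lists were cell cycle with 1 measured gene, cholesterol and lipid with 3, microglia and macrophage with 1, fibroblast, meningeal and vascular with 4, and housekeeping and ribosomal with 1.

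Genes were named by rule. Against control at each time these were the 5 largest changes in each direction past the threshold with all 3 exposed arrays on the same side of the control mean. For differences between times and the trend they were the 3 largest in each direction, and for the mean of the times up to 12. For each list up to 4 members past the threshold were named. Where none passed, the 3 smallest p-values in each direction were given as values. Gfap, Vim, S100b, Glul, Slc1a2, Slc1a3, App, Apoe and Fn1 were to be named wherever measured. Members of called lists that do not pass are given as examples chosen after their values were seen.

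The procedure was tested on simulated data with the same group sizes, spread and 1027 probe sets. At 12 hours against control it recovered 12%, 28%, 82% and 98% of probe sets changed by log2 0.5, 1, 2 and 3, and the share of unchanged probe sets called stayed at or below 0.73%. For 5 days against 12 hours it recovered 6%, 34%, 82% and 84%. The simulated noise was independent between probe sets and arrays and held no array clusters, which took 47.9% of the sum of squares in the real data. The recovery and the share of unchanged probe sets called therefore hold only for data without such clusters.

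The arrays were clustered by average linkage on 1 minus the Pearson correlation of log2 values, with the tree divided into 2 and into 5 clusters. Arrays with the same replicate number deviated together in the 1 day and 3 days groups, with correlations of their deviations from the group means of 0.390, 0.429 and 0.683, and in no other 2 groups did all 3 pairs exceed 0.1. A pairing would come from the values and not from the labels. In both groups array 3 alone lay in cluster 1, so arrays 1 and 2 deviate together from it in any pairing. These correlations therefore cannot tell a pairing of the numbers from the clusters. A replicate block in these 2 groups alone was added after seeing the data. Fits with the clusters as a block, camera with the block and an estimated correlation, fits within each cluster, and without 1 day array 3 and 3 days array 3 were added after seeing the data. The other alternatives were quantile normalization, centring on the median and cyclic loess, floors at the 1st and 25th percentiles, no filter and a filter at the 50th percentile, a robust fit with an intensity trend, array weights, a replicate block, only the groups compared, leaving out controls 1 and 2, and leaving out each array in turn. Overlap between comparisons that share the controls was set against 100 simulated draws of unchanged groups, against independent lists, and against split controls. Other splits of the arrays into groups of the same sizes were refitted, at most 100 per comparison. Figures were drawn with matplotlib 3.10.9 on Python 3.11.15.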

Results

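Gene expression was measured in rat cortical type-I astrocytes on 18 arrays of 1322 probe sets made for neurobiology genes. In 12 samples the cells had grown on an immobilized fragment of the beta-amyloid peptide, residues 25 to 35, for 12 hours, 1 day, 3 days or 5 days, with 3 samples per time. The 6 control samples came from cells on laminin and nitrocellulose without the peptide, and their labels give no time in culture. The labels of controls 1 and 2 name cerebral cortex as the source and astrocytes in the title. Those of the other 16 samples name type-I astrocytes as the source. The 2%-trimmed mean signal was 502.067 to 502.632 on every array, the median signal 101.6 to 133.1, and 6.33% to 12.5% of probe sets per array lay at or under the floor of 11.3. After the control probe sets were left out and dim ones were filtered, 1027 probe sets were tested, of which 926 carried 1 symbol and stood for 621 genes. The number of arrays limits the precision. The labels do not say that the samples were separate cultures, so the p-values measure the spread between these samples, which may be technical.

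The arrays fell into 2 clusters that did not follow the groups. Of 10 measured astrocyte markers, Slc1a3, S100b and Mt3 were lower in cluster 1 without overlap, Gja1 was higher, and 6 overlapped. The clusters were cut from these same values, so some genes with separate ranges are bound to occur. The share among all probe sets was not computed, so these genes do not show that the clusters differ in glial genes in particular. Slc1a3, a glial glutamate transporter, had signals of 259.8 to 654.8 in cluster 1 and 1556.2 to 4874.2 in cluster 2. S100b, a calcium-binding protein of astrocytes, had 19.7 to 401.2 against 528.6 to 1209, and the metallothionein Mt3 had 91.9 to 474.3 against 694.5 to 4629.4. Gja1, which encodes the gap junction protein connexin 43, went the other way, with 4269.5 to 11591.7 against 810.6 to 3116.5. Igf2, a growth factor, also had higher signals in cluster 1, 3282.5 to 8743.8 against 211.2 to 645.3. Igf2 and Map2, a neuronal microtubule protein with 31.1 to 74 against 241.1 to 631.9, came from the fixed marker lists, and these 6 genes were chosen after their values were seen. Cluster 1 held 7 arrays, which were controls 1 and 2, all 3 arrays at 12 hours, 1 day array 3 and 3 days array 3. Cluster 2 held the other 11 arrays, with controls 3 to 6 and all 3 arrays at 5 days. The clusters took 47.9% of the total sum of squares with 1 degree of freedom, and the 5 groups took 39.6% with 4. Arrays of 1 group had a median correlation of 0.955 within a cluster and 0.810 across clusters, while arrays of different groups in 1 cluster had 0.917. Every comparison is therefore given with the cluster as a block and within each cluster where its groups were present. The tree divided into 5 clusters put control 1 with the 3 arrays at 12 hours, control 2 with 1 day array 3 and 3 days array 3, control 3 with 3 days arrays 1 and 2, and controls 4 to 6 with the 3 arrays at 5 days. With these 5 clusters as a block, the fold at 12 hours compares with control 1 alone, the fold at 1 day rests on array 3 alone, and the lone array is assumed to vary like the other groups. A call lost in that fit therefore does not show that the call depends on the cluster. The labels do not pair controls with exposure times, so a fold against all 6 controls may compare cells of different preparations or times in culture. For called genes and lists a value or range with the 5 clusters as a block is given too, and the block without a number means the 2 clusters. Cluster 1 held 1 array at 1 day and 1 at 3 days, and in fits within cluster 1 such a lone array is assumed to vary like the other groups. The clusters were defined from the same values, so p-values of the blocked fits may be too small.

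**Figure D1:**
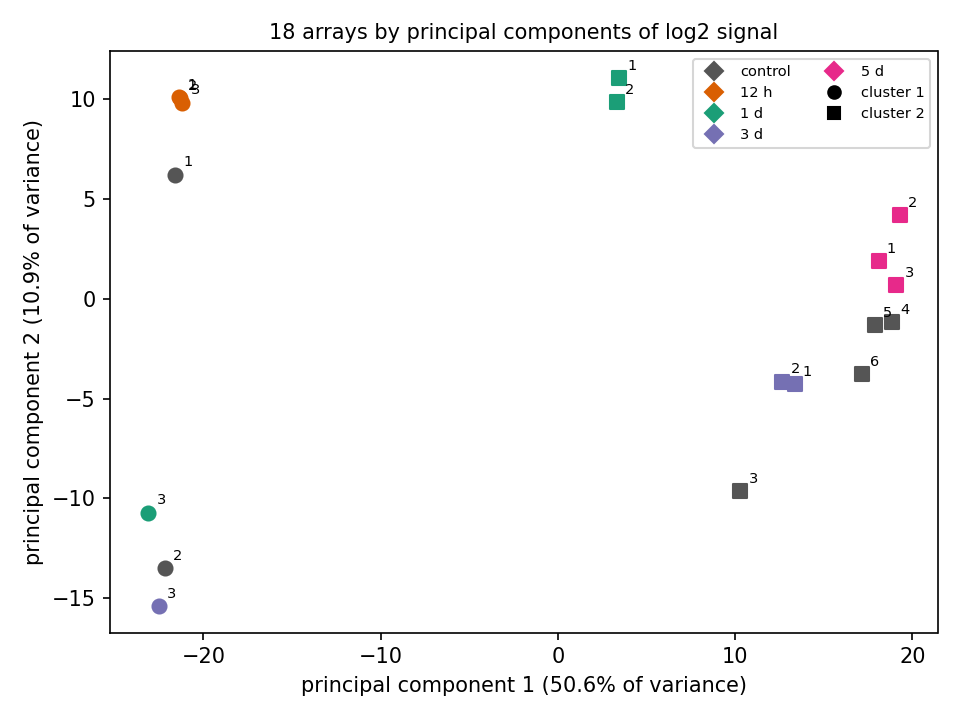
Principal components 1 and 2 of the log2 signal of the 18 arrays, in units of component score, with 50.6% and 10.9% of the variance; colours give the 5 groups, circles cluster 1, squares cluster 2, and numbers the replicate. Component 1 separates the 7 arrays of cluster 1 from the 11 of cluster 2, and controls and the 1 day and 3 days groups have arrays on both sides.

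The question of the comparison at 12 hours was which genes differed after the shortest exposure. Ccl5, a chemokine that attracts T cells and monocytes, and Ptgs2, the inducible enzyme of prostaglandin synthesis, rose. The cytokine receptor kinase Jak2, the hepatocyte growth factor receptor Met, the fibroblast growth factor receptor Fgfr1, the mitochondrial chaperonin Hspd1 and Glul, which makes glutamine from glutamate, rose as well. The potassium channel gene Kcnma1 rose on 1 of its 2 probe sets. Nalcn, a sodium leak channel, fell below the floor on all 3 arrays, and the amino acid transporter Slc6a15, the brain protein gene Ctxn1, the ligand Cd40lg, the protein kinase A inhibitor Pkia, the synaptic vesicle protein Syn1 and, on 1 of its 2 probe sets, the nicotinic receptor subunit Chrnb4 fell.

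By limma at an adjusted p of 0.05, 17 probe sets differed from the controls at 12 hours, 8 higher and 9 lower, and 301 had an unadjusted p under 0.05 against 51.4 by chance. Nalcn had a signal of 101 ± 32.2 (SD, n = 6) in the controls and 8.17 ± 1.72 (SD, n = 3) at 12 hours, which was at least 8.41-fold lower with a limma adjusted p of 0.00127. It was lower in 3 of 3 arrays, and its other probe set fell by 2.36 on the log2 scale with a limma adjusted p of 0.0406. With the 2 clusters as a block, the Nalcn fold was -2.90 with a limma adjusted p of 0.0156, and within cluster 1 it was -2.49. With the 5 clusters as a block the only control compared is control 1, which had the lowest Nalcn signal of the 6, and the fold was -1.89 with a limma adjusted p of 0.0963, and no probe set passed at 12 hours. Nalcn was the only call shared with the blocked fit, which called 3 probe sets, 1 higher and 2 lower, and the fit within cluster 1 called 0. Cluster 2 held no array at 12 hours.

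Ccl5 rose by 5.32 ± 1.11 (SE) on the log2 scale with a limma adjusted p of 0.0382, from 1250.5 to 1480 at 12 hours against 11.4 to 24.2 on 5 controls, but control 1 had 1496.3. Its fold was 3.96 with the block, with a limma adjusted p of 0.117, 2.80 within cluster 1 and -0.18 with the 5 clusters. Ptgs2 rose by 2.59 ± 0.62 (SE) with a limma adjusted p of 0.0475, from 527 ± 485 (SD, n = 6) to 2311 ± 155 (SD, n = 3), and had folds of 2.33 with the block, limma adjusted p 0.133, 1.16 within cluster 1 and 0.71 with the 5 clusters. The Glul probe set rc_AI012265_i_at rose by 0.92 ± 0.21 (SE) with a limma adjusted p of 0.0439, with folds of 0.94 with the block, 0.93 within cluster 1 and 0.40 with the 5 clusters, and its 3 other probe sets had 0.63 to 0.95 without passing. Kcnma1 rose by 1.64 ± 0.34 (SE) on probe set U55995_at, with a limma adjusted p of 0.0382, and its other probe set had -1.42 without passing.

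Jak2 rose by 1.28, Met by 1.17, Fgfr1 by 0.79 and Hspd1 by 0.77, while the 2 other Jak2 probe sets had 0.01 and 0.53 and the other of Fgfr1 had 0.48, none past the threshold. With the block the folds were 1.86 for Kcnma1, 0.86 for Jak2, 0.89 for Met, 0.64 for Fgfr1 and 0.67 for Hspd1, and with the 5 clusters they were 1.78, 0.67, 0.29, 0.29 and 0.45. Slc6a15 had a fold of -2.56, Ctxn1 -1.71, Cd40lg -1.21, Pkia -1.05, Chrnb4 -0.85 and Syn1 -0.71, while the other Chrnb4 probe set had 0.19 with a limma adjusted p of 0.738. With the block Slc6a15 had -1.82, Ctxn1 -1.15, Cd40lg -1.07, Pkia -0.74, Chrnb4 -0.72 and Syn1 -0.62, and with the 5 clusters they had -1.23, -0.22, -0.71, -0.50, -0.32 and -0.26. None of these 11 genes passed by limma in either blocked fit. Among the astrocyte genes, on the probe sets with the highest signal, Vim had 0.25, S100b -0.19, Slc1a2 -0.44, Slc1a3 -1.25 and Apoe 0.01. The Glul probe set with the highest signal had 0.63, and none of these passed by limma.

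The called genes named at 12 hours other than Nalcn had limma adjusted p-values of 0.0382 to 0.0477, near the threshold. Leaving out an array of another time changes only the shared spread of the fit, not the fold at 12 hours. The count at 12 hours moved with the array left out and with the scaling. It was 211 without control 1, 31 without control 2, 8 without 5 days array 1, 4 without 3 days array 1, and 1 or 2 without any 1 of controls 3 to 6, of the 3 arrays at 12 hours, of 1 day arrays 1 and 2, of 3 days array 2 or of 5 days arrays 2 and 3. Ccl5, Ptgs2 and Glul lost the call without most of these arrays, while their folds were then 5.02 to 5.36, 2.36 to 2.63 and 0.85 to 0.99. Quantile normalization called 7 higher and 1 lower, centring on the median 10 and 5, and cyclic loess 4 and 1. The median log2 fold of all tested probe sets at 12 hours was -0.18 as deposited, -0.01 after quantile normalization, 0.02 after centring and -0.04 after cyclic loess. No gene list passed with camera at 12 hours, and the smallest adjusted p was 0.132, shared by several lists, among them cytokines and inflammation, extracellular matrix, and potassium, sodium and calcium channels. With the block, camera called 6 lists higher, with adjusted p-values of 0.00654 for astrocyte markers, 0.00876 for reactive astrocyte genes, 0.00949 for glutamate handling, and 0.0280 for growth factors, heat shock and cytoskeleton genes. With the block and an estimated correlation these had 0.0803 to 0.165, and 0 of the 19 lists passed either there or with the 5 clusters. The median fold of the astrocyte markers was -0.09 without the block and 0.78 with it. Adjusted over the list alone, Ccl5 and Ptgs2 passed among 23 cytokine genes, and Cd44 higher and Agrn, Ncam1 and Bcan lower passed among 13 matrix genes.

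**Figure D2:**
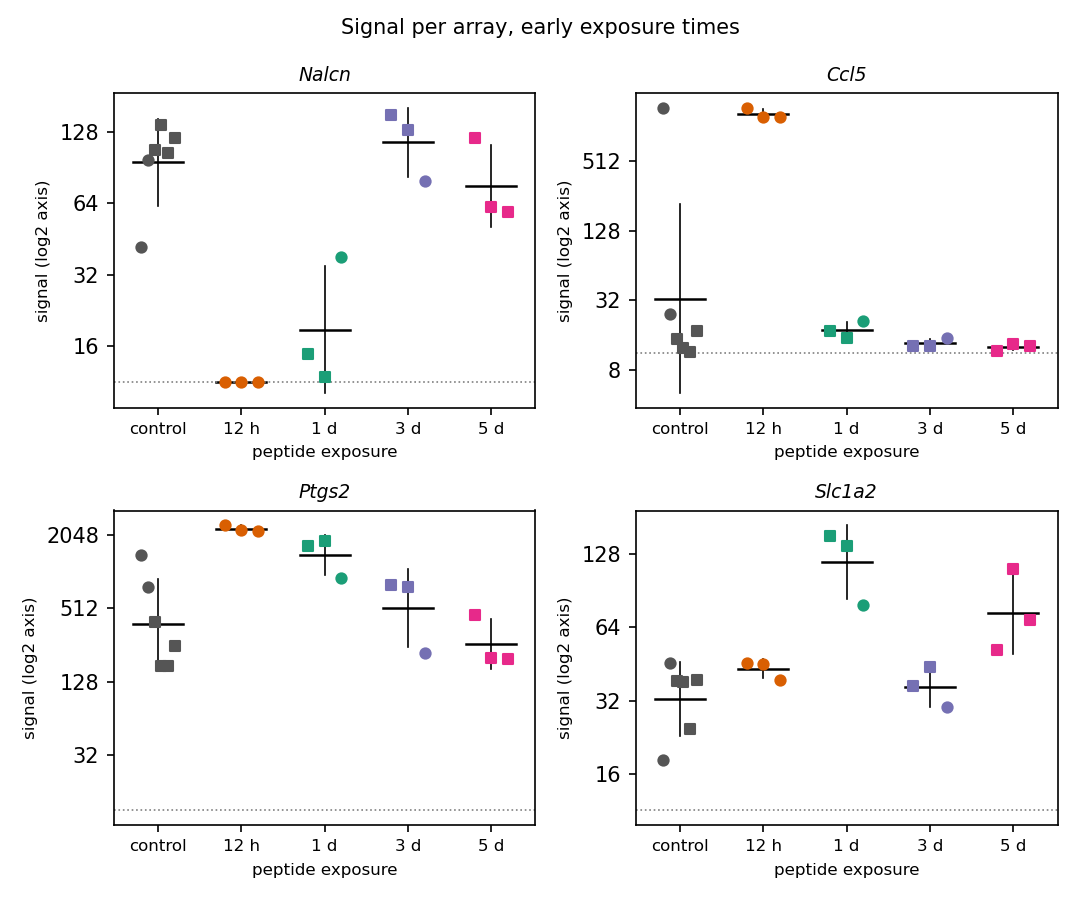
Signal per array on a log2 axis for Nalcn, Ccl5, Ptgs2 and Slc1a2 (probe set rc_AI044517_g_at) in the controls and at 4 exposure times; points are arrays (circles cluster 1, squares cluster 2), bars the mean of the log2 values ± 1 SD, and the dotted line the floor of 11.3. Nalcn lies at the floor on all 3 arrays at 12 hours, and control 1 has a Ccl5 signal of 1496.3.

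After 1 day the glutamate transporter gene Slc1a2, which clears glutamate around synapses, rose on 1 of its 3 probe sets. Nalcn remained below the controls. Tacr3, the receptor of the peptide neurokinin B, fell. Of the genes often used to describe astrocytes, Vim, S100b, Slc1a3 and Apoe had folds of 0.00, -1.18, 0.03 and -0.18 on the probe sets with the highest signal and did not pass, and the other S100b probe set had 0.09. The Glul probe set with the highest signal had -0.10 and did not pass.

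By limma 3 probe sets passed at 1 day, 1 higher and 2 lower, and 120 had an unadjusted p under 0.05. Slc1a2 had a signal of 34.0 ± 10.4 (SD, n = 6) in the controls and 124 ± 39.0 (SD, n = 3) at 1 day on probe set rc_AI044517_g_at, a rise of 1.88 ± 0.31 (SE) on the log2 scale with a limma adjusted p of 0.0151. With the block Slc1a2 had 1.88 with a limma adjusted p of 0.00498, and it had 1.46 within cluster 1, where 1 array at 1 day was set against 2 controls, and 2.08 within cluster 2. Its probe set rc_AI044517_at had 1.21 and U15098_at had 0.13, with limma adjusted p-values of 0.389 and 0.946. Nalcn fell by 2.34 ± 0.40 (SE) with a limma adjusted p of 0.0151 and had -0.75 within cluster 1 and -3.14 within cluster 2, and its other probe set fell short with -1.51 and an adjusted p of 0.317. Tacr3 fell by 1.89 ± 0.37 (SE) with a limma adjusted p of 0.0399 and had -2.29 within cluster 1 and -1.68 within cluster 2. All 3 were among the 30 probe sets, 12 higher and 18 lower, that limma called with the block, where Nalcn and Tacr3 had an adjusted p of 0.00831. With the 5 clusters as a block, where only array 3 informs the fold at 1 day, none of the 3 passed, with folds of 0.98 for Slc1a2, -1.16 for Nalcn and -2.58 for Tacr3 and limma adjusted p-values of 0.766, 0.455 and 0.118, and 1 other probe set passed. The fit within cluster 1, with its 1 array at 1 day, called 0 and that within cluster 2 called 123. Without 1 day array 1 limma called 0, without array 2 it called 1, and without array 3 it called 26. It called 7 without control 1, 6 without control 2, and 59 without both. With 1 day array 1 or 2 left out, Slc1a2 had 1.70 and 1.77 and Nalcn -2.17 and -2.01, and neither passed. Tacr3 lost the call without 1 day array 1 or 3, control 3, 5 or 6, 12 hours array 2, or any array at 3 or 5 days, with folds of -1.90 to -1.50 and limma adjusted p-values of 0.0558 to 0.278. Each of the other 3 scalings called 2 higher and 2 lower. No gene list passed with camera at 1 day.

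At 3 days no gene passed, and the values with the smallest p are given without a direction of change. Nrp2, a receptor of semaphorins, had a fold of 0.85 with a limma adjusted p of 0.452. Gad1, which makes the transmitter GABA, had -1.17, and the transcription factor genes Nr4a1 and Jun had -1.45 and -0.70, with -1.36 on the other Nr4a1 probe set. Chrna7 had 1.39 on 1 probe set and -1.17 and -0.26 on its other probe sets, and Hrk, a promoter of cell death, had 1.48 on 1 probe set and 0.18 and -0.52 on its other probe sets. As a list, 12 immediate early genes, which respond quickly to stimuli, were lower with camera at an adjusted p of 0.0382, and the adjusted p was 0.588 with an estimated correlation. Junb had -0.94, Fos -0.81 and Egr1 -0.63, and of the 12 genes 0 passed over all probe sets and 1, Nr4a1, adjusted over the list alone. Quantile normalization gave this list an adjusted p of 0.0556, the block 0.0892 and the 5 clusters 0.712. By limma 0 probe sets passed at 3 days, 47 had an unadjusted p under 0.05 against 51.4 by chance, and 0 passed with the block and 6 within cluster 2. Within cluster 1, where 1 array at 3 days was set against 2 controls, 1 passed, under the assumption that the lone array varies like the other groups. Without 3 days array 3 limma called 3. Among the astrocyte genes, on the probe sets with the highest signal, Vim had -0.02, S100b -1.12, Glul -0.45, Slc1a2 -0.40, Slc1a3 -0.29 and Apoe -1.08.

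At 5 days no single gene passed by limma against the controls, while camera at its preset correlation called 2 lists higher, astrocyte markers and oxidative stress with metallothionein genes. Neither list passed with an estimated correlation, with adjusted p-values of 0.301 and 0.152. Tf, which encodes the iron carrier transferrin, had a fold of 2.56 ± 0.49 (SE) on 1 probe set and 1.33 on another, both with a limma adjusted p of 0.0804, and 1.43 on its other probe set. The complement gene C3 had 3.03 and the sodium pump subunit Atp1b2 1.31, and Ifng had -1.14, each with a limma adjusted p of 0.206. The other C3 probe set had 0.97 with a limma adjusted p of 0.520, and the other of Atp1b2 had 1.70 with 0.503. Slc18a2 had -0.95 and Grin2c -0.97, with -0.23 on the other Grin2c probe set. In the list of 10 astrocyte markers, Mt3 had 2.25, Slc1a3 1.64, Apoe 1.22, S100b 1.14 and Gja1 -0.72, and camera gave an adjusted p of 0.0193, which was 0.301 with an estimated correlation. The other S100b probe set had -0.25 and the 3 others of Slc1a3 had 1.83, 1.82 and -0.57. Mt3, Slc1a3 and S100b also separated the 2 clusters, and with the block Mt3 had 1.17, Slc1a3 0.60, Apoe 0.80 and S100b -0.23. In the list of 9 oxidative stress and metallothionein genes, Mt2A had 2.29, Mt1 1.05, Gsta1 1.11 and Sod2 -0.64, and camera gave 0.0193, which was 0.152 with an estimated correlation. With the block both lists had an adjusted p of 0.0390, as did the GABA, glycine and acetylcholine receptors, which were lower as a list. With the block and an estimated correlation the adjusted p was 0.365 for astrocyte markers and the receptors and 0.275 for the oxidative stress list. With the 5 clusters the oxidative stress list had 0.00698, astrocyte markers 0.0510 and the receptors 0.310, and after cyclic loess the astrocyte and oxidative stress lists had 0.0514. Adjusted over the list alone, 0 astrocyte markers and 0 oxidative stress genes passed. By limma 0 probe sets passed at 5 days, 94 had an unadjusted p under 0.05, and 0 passed with the block or within cluster 2, while cluster 1 held no array at 5 days. Limma called 2 without control 6 and 1 without control 4. Vim had 0.15 at 5 days, and the Glul and Slc1a2 probe sets with the highest signal had 0.15 and -0.04.

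Over the mean of the 4 exposure times no gene passed. Slc1a2 had a fold of 0.91, Gsta1 0.85 and Fgfr1 0.47, and Nalcn -1.37, Kcna4 -0.74 and Nptxr -0.53, and the smallest limma adjusted p was 0.217, that of Nalcn. The other Nptxr probe sets had 0.36 and 0.44, those of Slc1a2 0.27 and -0.19, and the other of Gsta1 had 0.40, of Fgfr1 0.23 and of Nalcn -0.96. Of the astrocyte genes, Vim had 0.10, Slc1a3 0.03, Apoe -0.01 and S100b -0.34, and the Glul and Slc1a2 probe sets with the highest signal had 0.06 and -0.19. No probe set with the single symbol Gfap, App or Fn1 was tested here. The 6 heat shock and ER stress genes were higher as a list with camera at an adjusted p of 0.0301, which was 0.120 with an estimated correlation, 0.137 after quantile normalization, 0.0808 with the block and 0.174 with the 5 clusters. In it Hspd1 had 0.33, Hspe1 0.32, Hsp90ab1 0.20 and Hspb1 -0.50, and 0 of them passed over all probe sets. By limma 0 probe sets passed, 77 had an unadjusted p under 0.05, and 0 passed with the block. Within cluster 1 the mean covered 12 hours, 1 day and 3 days and 1 passed, and within cluster 2 it covered 1, 3 and 5 days and 33 passed, so neither is the mean of the 4 times. Limma called 3 without control 1, 1 without control 6, 1 without 1 day array 3, and 54 without controls 1 and 2.

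The comparisons of consecutive times ask when expression moved. Between 12 hours and 1 day the neurofilament gene Nefl had 2.97, the opioid precursor gene Penk 3.67, Nrp2 1.05, Ccl5 -6.24, Glul -1.04 and Th -1.82, and none passed by limma, with adjusted p-values of 0.0709 for Nefl, Penk, Nrp2 and Ccl5 and 0.0846 for Th. The other Penk probe set had 0.15 with a limma adjusted p of 0.811 and the other of Nefl 1.65 with 0.348, and the 3 others of Glul had -0.87 to -0.68. With the block, Nefl had 2.30 and Nrp2 1.06, each with a limma adjusted p of 0.0470, and Penk 2.35 with 0.0349. The folds with the 5 clusters as a block were 1.79 for Nefl, 0.44 for Nrp2 and 0.50 for Penk, each with a limma adjusted p of 0.997, and they rest on 1 day array 3 and on control 1. By limma 0 probe sets passed, 150 had an unadjusted p under 0.05, and 15 passed with the block, 7 higher and 8 lower, and 0 within cluster 1, with 1 array at 1 day. Limma called 24 without 1 day array 3, 14 without control 1 and 2 without 3 days array 3. The 12 immediate early genes were lower at 1 day than at 12 hours with camera at an adjusted p of 0.0279, which was 0.513 with an estimated correlation, 0.0623 with the block and 0.972, with the other sign, with the 5 clusters. In it Fosl1 had -2.64, Cebpb -1.82, Junb -1.21 and Egr1 -0.92, and 3 genes passed adjusted over the list alone.

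Between 1 and 3 days Nalcn rose by 2.62 ± 0.46 (SE) on the log2 scale with a limma adjusted p of 0.0424, to 119 ± 36.3 (SD, n = 3). With the block its limma adjusted p was 0.0231, with the 5 clusters, where 1 day is array 3 alone, its fold was 1.26 with 0.252, and its other probe set had 1.48 with 0.550. With the replicate number of these 2 groups as a block, Nalcn had the same fold with a limma adjusted p of 0.0912, which ended the call, and limma called 0. With a replicate block over all groups Nalcn had 0.106, limma called 2 other probe sets, both lower, and camera called the reactive astrocyte genes lower with an adjusted p of 0.0232, which was 0.170 with an estimated correlation. Nalcn was the single probe set of 1027 that passed by limma, 86 had an unadjusted p under 0.05, and 13 passed with the block, 6 higher and 7 lower, and 38 within cluster 2, where 2 arrays were compared with 2. Cluster 1 held 1 array of each time, and the fit within it called 1 under the assumption that these lone arrays vary like the other groups. The call was lost without 1 day array 1 or 2, 3 days array 1 or 2, controls 2 to 5, any array at 12 hours, or 5 days array 2 or 3, with folds of 2.29 to 2.62 in each. Limma called 10 probe sets without 1 day array 3, 3 without control 1, and 2 without control 6 or without 3 days array 3. Centring and quantile normalization called 3, 1 higher and 2 lower, and cyclic loess 1 and 1.

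Between 3 and 5 days Tf and C3 rose. The controls varied widely too, from 11.6 to 78.8 for Tf on probe set U31866_g_at and from 9.4 to 171.1 for C3 on M29866_s_at. None of the 5 clusters held arrays of both times. From these arrays alone, time and those clusters therefore cannot be told apart, and the fit with the 5 clusters links the times only through the controls. Tf went from 10.8 ± 4.54 (SD, n = 3), with 2 of 3 arrays at the floor, to 128 ± 29.6 (SD, n = 3), a rise of 3.32 ± 0.56 (SE) on the log2 scale with a limma adjusted p of 0.0136. A further Tf probe set rose by 1.88 with the same adjusted p in limma, and another had 1.66 with 0.218. C3 lay at the floor on all 3 arrays at 3 days and had 290 ± 126 (SD, n = 3) at 5 days, at least 23.6-fold higher with a limma adjusted p of 0.0334, and its other probe set had 2.14 with 0.0902. With the block Tf had 3.21 with a limma adjusted p of 0.0295 and C3 4.23 with 0.0583, and within cluster 2 Tf had 3.47. With the 5 clusters as a block both calls were lost, with 1.74 for Tf and 1.70 for C3 and limma adjusted p-values of 0.703 and 0.841. These were the 3 probe sets past the threshold by limma, 118 had an unadjusted p under 0.05, 2 passed with the block, both of them among the 3, and 0 within cluster 2. Limma called 0 without 3 days array 1 or 3 or 5 days array 1 or 3, 1 without 3 days array 2, 2 without any array at 12 hours, 1 day arrays 1 or 2 or 5 days array 2, and 6 to 12 without any 1 control.

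As lists, astrocyte markers with Apoe at 2.30, Mt3 at 2.27, S100b at 2.26 and Slc1a3 at 1.92 were higher at 5 than at 3 days, with an adjusted p of 0.00336 by camera and 0.168 with an estimated correlation. Against control at 3 days, S100b went from -1.12 to 0.53 and Slc1a3 from -0.29 to 0.73 without 1 day array 3 and 3 days array 3. Their rise thus rests in part on 3 days array 3, of cluster 1. Another S100b probe set had -0.01 at 3 days and -0.25 at 5 days against control. The Slc1a3 probe set X63744_at had 0.10 and -0.57, S75687_s_at -0.38 and 1.83 and X63744_g_at -0.02 and 1.82. Reactive astrocyte genes with Mt2A at 3.96, C3 at 2.14 on its other probe set, Mt1 at 1.84 and Vcam1 at 1.32 were higher with 0.0474 by camera and 0.168 with an estimated correlation. Immediate early genes with Nr4a1 at 2.27 and Jun at 0.98 were higher with 0.00704 by camera and 0.168 with an estimated correlation. Glutamate handling and cytoskeleton genes were higher with 0.0474 by camera and 0.204 with an estimated correlation. With the block, astrocyte markers and immediate early genes had 0.00136 and glutamate handling 0.0300, while reactive astrocyte genes had 0.0883 and cytoskeleton genes 0.161. With the block and an estimated correlation these lists had 0.188 to 0.259, and with the 5 clusters each had 0.988. Adjusted over the list alone, 4 reactive astrocyte genes and 2 immediate early genes passed.

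The arrays at 5 days and at 12 hours lay in different clusters, so that time and cluster cannot be told apart in this comparison. Cacna2d1, an auxiliary subunit of calcium channels, was at the floor on all 3 arrays at 12 hours and at 951 ± 39.95 (SD, n = 3) at 5 days, at least 84.1-fold higher. The growth factor binding protein gene Igfbp3 rose by 5.87 and the adhesion protein gene Lsamp by 5.67. Ccl5, the transcription factor gene Foxd1 and the neuropeptide gene Sst fell, with folds of -6.71 ± 1.28 (SE), -5.76 and -5.72. The limma adjusted p was 0.0448 for Cacna2d1 and Foxd1, 0.0496 for Igfbp3, 0.0269 for Lsamp, 0.0107 for Ccl5 and 0.0446 for Sst. The values of Igfbp3 are those of probe set M31837_at, and rc_AI009405_s_at had 5.71 with a limma adjusted p of 0.0415. Those of Sst are of M25890_at, and K02248cds_s_at had -3.53 with a limma adjusted p of 0.0409. With the block the folds were 0.58 for Cacna2d1, 0.40 for Igfbp3, 2.27 for Lsamp, -4.66 for Ccl5, -0.60 for Foxd1 and -0.62 for Sst, and none passed. With the 5 clusters as a block, and so with control 1 alone as the link to 12 hours, they lay between -1.47 for Igfbp3 and 0.19 for Cacna2d1, and none passed.

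By limma 169 probe sets of 120 genes differed between 5 days and 12 hours, 92 higher and 77 lower, 328 had an unadjusted p under 0.05, and 0 passed with the block. The median size of the fold among the 169 was 1.78 without the block and 0.75 with it, and all 169 kept their sign. The count was 1 without 12 hours array 2, 12 and 11 without arrays 1 and 3, 33 without 5 days array 1, 10 without 5 days array 2 or 3, and 96 and 76 without 1 day arrays 1 and 2. Calls were 54.4% higher as deposited, 46.7% after quantile normalization and 43.5% after centring on the median, where 70 were higher and 91 lower, and 57.7% after cyclic loess, where 90 were higher and 66 lower. No gene list passed with camera.

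Over the 4 exposure times, Lsamp rose by 1.72, Igfbp3 by 1.59 and Pcp4, a calmodulin-binding protein gene at the floor on all arrays at 12 hours, by 1.501 per doubling of the hours. Ccl5, Foxd1 and Gal, a neuropeptide gene, fell, with slopes of -1.74, -1.53 and -1.44. The limma adjusted p was 0.0183 for Lsamp and Gal, 0.0350 for Igfbp3, 0.0366 for Pcp4, 0.0117 for Ccl5 and 0.0487 for Foxd1. The values of Igfbp3 for the trend are those of probe set rc_AI009405_s_at. Its probe set M31837_at had a slope of 1.58 and did not pass, with a limma adjusted p of 0.0552. With the block the slopes were 0.88 for Lsamp, 0.41 for Igfbp3, 0.48 for Pcp4, -1.24 for Ccl5, -0.25 for Foxd1 and -1.01 for Gal, and none passed by limma, with adjusted p-values of 0.108 to 0.374. With the 5 clusters they lay between -0.08 for Pcp4 and 0.16 for Igfbp3. The arrays at 12 hours and 5 days, the ends of the trend, lay in different clusters. By limma 144 probe sets of 108 genes had a trend, 78 rising and 66 falling, 321 had an unadjusted p under 0.05, 2 passed with the block, both among the 144, and 0 with the 5 clusters. Quantile normalization gave 52 rising and 58 falling, centring on the median 67 and 83, and cyclic loess 72 and 59. The count was 11, 16 and 13 without 12 hours arrays 1, 2 and 3, 65, 41 and 16 without 5 days arrays 1, 2 and 3, 59, 73 and 225 without 3 days arrays 1, 2 and 3. The moderated F-test over the 5 groups called 17 probe sets, 258 had an unadjusted p under 0.05, and 26 passed with the block, of which 9 were shared. That count was 114 without control 1, 37 without control 2, 47 without 1 day array 3, 24 without 3 days array 3, and 1 to 11 without any 1 of the other 14 arrays.

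**Figure D3:**
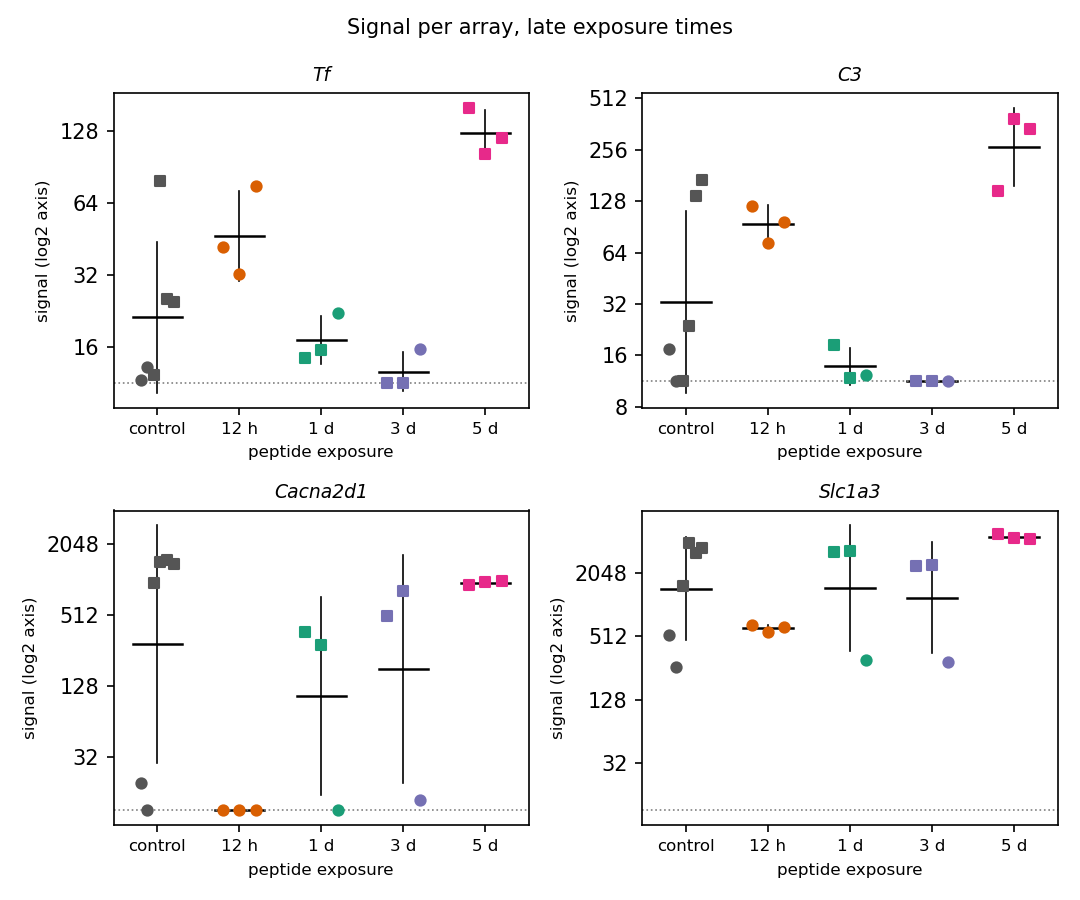
Signal per array on a log2 axis for Tf, C3, Cacna2d1 and Slc1a3 in the controls and at 4 exposure times; points are arrays (circles cluster 1, squares cluster 2), bars the mean of the log2 values ± 1 SD, and the dotted line the floor of 11.3. For Cacna2d1 and Slc1a3 the arrays of cluster 1 lie below those of cluster 2 in every group that has both.

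**Figure D4:**
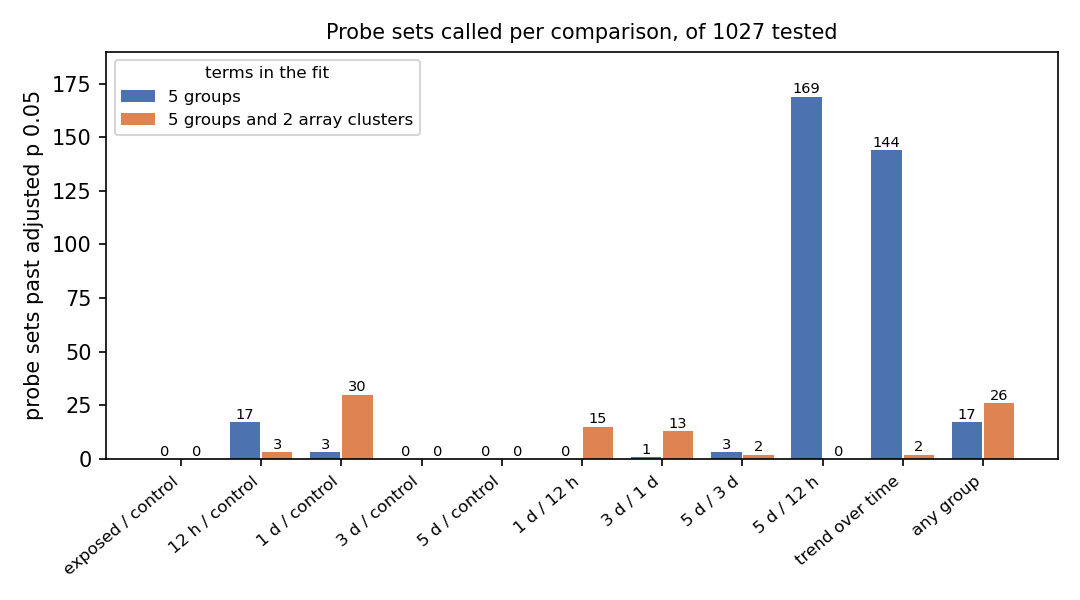
Number of probe sets past an adjusted p of 0.05 among 1027 tested, per comparison, in the limma fit with the 5 groups and in the fit with the 5 groups and the 2 clusters. The count of 169 between 5 days and 12 hours becomes 0 with the clusters in the fit, and that of the 1 day comparison goes from 3 to 30.

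The 4 comparisons against control shared the 6 control arrays. Nalcn was the single probe set called in the same direction in more than 1 of them, at 12 hours and 1 day. In each of 100 simulated draws of unchanged groups 0 calls were shared, and independent lists would share 0.0253. The draws replaced all 18 arrays, controls included, by independent noise without array clusters. They therefore cannot stand for the shared controls of these data. With controls 1 to 3 used at 12 hours and 4 to 6 at 1 day, 4 and 95 probe sets were called and 1 was shared, with 0.184 expected, and with the sets exchanged 311 and 1 were called and 1 was shared, with 0.132 expected. Against controls 1 to 3, 58 probe sets were called at 5 days. In the same direction these shared 0 with the 311 at 12 hours and 0 with the 95 at 1 day, where 8.44 and 2.67 were expected. Calls of opposite direction were not counted as shared in any split. Controls 1 and 2 and the arrays at 12 hours lay in cluster 1, and controls 4 to 6 and the arrays at 5 days in cluster 2. The pair of 5 days and 12 hours thus also sets the clusters against each other in opposite directions, and its 0 does not show separate responses. The other split pairs shared 0, with at most 0.647 expected. The overlap was 0 without 1 day array 1 or 2, 2 without control 6, 3 without 1 day array 3 and 5 without control 1.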

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

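The tests of the cluster of the arrays, the exposure time, RNA degradation, exposure to the peptide, fewer astrocytes and the controls compared were chosen only after results were seen, while the test of the scaling and the splits of the arrays were written before their values were seen.

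Of 49 probe sets tested for a control array far from the other 5, 5 had one, and chance alone would find about 1 in 20. Control 1 had a Nalcn signal of 41.8 against 96.8 to 135.9 on the other 5 controls and a Ccl5 signal of 1496.3 against 11.4 to 24.2. Control 2 had an S100b signal of 19.7 against 401.2 to 1209. Control 3 had an Slc1a2 signal of 36.5 against 80.7 to 107.4 on probe set U15098_at, and control 6 a Kcnma1 signal of 43.9 against 4.8 to 13.8 on U55995_at.

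The exposure times differed from one another by limma in 1 probe set between 3 days and 1 day, 3 between 5 days and 3 days, 169 between 5 days and 12 hours, and 144 in the trend over time. Among the 35 control probe sets, which no comparison of the report uses, limma found the spiked-in DapX-5 lower by -0.79 (adjusted p 0.0404) and Hexokinase_5 higher by 0.78 (adjusted p 0.0404) at 12 hours. At 1 day the spiked-in BioB-5 had -0.99 (adjusted p 0.0193) and BioB-M -0.85 (adjusted p 0.00967). No explanation of these control probe sets was tested.

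The arrays formed 2 clusters, of 7 and 11 arrays, that divided the controls and the 1 day and 3 days groups. Scaling by a constant factor per array is argued against, because the clusters rest on correlations of log2 values, which such a factor leaves unchanged above the floor. Quantile normalization and cyclic loess also remove differences between arrays that depend on intensity. After each of them 100% of array pairs kept their status. This argues against such differences as the cause, as far as these methods remove them. Exposure to the peptide as the whole cause is argued against, since 2 of 6 controls lay in cluster 1. RNA degradation was not shown, since 0 of 3 transcripts had 3' to 5' ratios with separate ranges. Actin had 0.917 to 0.960 in cluster 1 and 0.867 to 0.953 in cluster 2. GAPDH had 0.955 to 1.24 and 1.11 to 1.33, and hexokinase 1.28 to 2.46 and 1.25 to 1.83. The rule of this test counted only separate ranges, so overlap could not argue against degradation, which stays open. Fewer astrocytes in the cultures of cluster 1 may contribute but stay open, because 3 of 10 astrocyte markers were lower there without overlap (Slc1a3, S100b and Mt3), 1, Gja1, was higher, and 6 overlapped, and a difference in preparation or time in culture was not tested because the labels give neither for the controls.

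For the 169 probe sets between 5 days and 12 hours, the cluster of the arrays is a candidate explanation. Of them 86.4% had the sign of the cluster difference measured within the other groups, against 70.3% of all probe sets, with a median ratio of 0.469 to the time difference. The 86.4% stayed under the share of 90% set for the cluster as the cause, so this test leaves the cause open. The controls alone, for which no share was set, had 96.4% with a median ratio of 0.679. With the clusters as a block 0 stayed past the threshold. The median size of the fold went from 1.78 to 0.75, and the median over probe sets of the share of the fold kept was 47.5%. The median SE went from 0.471 to 0.402, so the calls ended because the folds became smaller. Exposure time, the biological explanation in the design, and cluster cannot be told apart, because all arrays at 12 hours lay in cluster 1 and all at 5 days in cluster 2.

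For the 17 probe sets at 12 hours, the choice of controls may explain part of the differences. Against controls 1 and 2 alone, which lay in the same cluster as the arrays at 12 hours, the median fold was 61.5% of that against all 6, with a range of 44.6% to 117%, and all 17 kept their sign. Against control 1 alone 16 kept their sign with a median of 47.8%, and against control 2 alone 17 with 91.8%. Exposure to the peptide remains open as the explanation of the rest, since the controls are 2 arrays that differ between themselves. Without controls 1 and 2, limma called 321 probe sets, 135 higher and 186 lower.

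At 12 hours against control 3 of 84 splits called as many as the real 17, a share under 0.05. The highest other split there, which put controls 4 to 6 together, called 226. The share was also under 0.05 for the F-test, where 1 of 100 splits reached the real 17 with 11 as the highest other. For the trend 2 of 100 reached 144, with 169 as the highest other. The shares were not adjusted over the comparisons, so chance in the grouping is made less likely there but is not excluded. These splits exchanged arrays across the clusters, so they exclude nothing about the clusters, and with the 2 and 5 clusters as a block limma called 2 and 0 for the trend and 26 and 3 for the F-test. In the 5-cluster fit 12 hours is compared with control 1 alone and 1 day rests on array 3 alone, each assumed to vary like the other groups. At 1 day 8 of 84 splits reached 3 with 190 as the highest other, a share over 0.05. The share was also over 0.05 at 3 days (84 of 84 reached 0, highest other 276) and at 5 days (84 of 84 reached 0, highest other 155). So it was for the mean of the 4 times (100 of 100 reached 0, highest other 114). At 1 day and 3 days the splits with the highest counts followed the 2 clusters. They put controls 1 and 2 and 1 day array 3 together, or controls 1 and 2 and 3 days array 3, which points to a structure of the samples. At 5 days that split put controls 1 to 3 together and at 12 hours controls 4 to 6, which parts control 3 from the other controls of cluster 2. With the clusters as a block limma called 3, 30, 0 and 0 at the 4 times, and with the 5 clusters 0, 1, 6 and 0.

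Between exposure times 3 arrays against 3 allow 10 splits, which are too few for a share under 0.05. The real counts and the highest others were 0 and 0 for 1 day against 12 hours (10 splits as high), 1 and 4 for 3 days against 1 day (3 splits, where the highest other of the 4 splits that part all 3 same-numbered pairs had 0 and the other 6 part 1 pair), 3 and 0 for 5 days against 3 days (1 split) and 169 and 0 for 5 days against 12 hours (1 split).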

How the results depend on the processing

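The tests with the clusters as a block, within each cluster, with the block and an estimated correlation together, without 1 day array 3 and 3 days array 3, and with the replicate block in the 1 day and 3 days groups alone were chosen only after results were seen, and the other alternatives were chosen before. Over 41 settings and 87 named results, 2235 values kept their direction and their side of the threshold, 501 lost the threshold, 72 passed it newly and 122 reversed. Most of the named results did not pass as fitted, and a value kept there only stayed short of the threshold. All 501 lost values belong to the results that passed as fitted, so the 2235 overstate how well the calls held. Nalcn at 12 hours kept its call in 31 of 34 settings, Slc1a2 at 1 day in 28 of 34, Nalcn at 1 day in 28 of 35, Tacr3 at 1 day in 15 of 34, Nalcn between 1 and 3 days in 14 of 36, C3 between 3 and 5 days in 18 of 34, Tf between 3 and 5 days in 26 of 33, Ccl5 at 12 hours in 16 of 34 and Ptgs2 in 12 of 34. The other called genes named at 12 hours kept it in 10 to 15 settings. Signals near the floor limit what dim genes can show. Where no cause is named for a moved count or a reversed value, the cause was not tested.

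Counts of probe sets past the threshold as fitted were 0 for the mean of the times, 17 at 12 hours, 3 at 1 day, 0 at 3 days, 0 at 5 days, 0 for 1 day against 12 hours, 1 for 3 days against 1 day, 3 for 5 days against 3 days, 169 for 5 days against 12 hours, 144 for the trend and 17 for the F-test, with 4 gene lists against control and an overlap of 1. Quantile normalization gave 8 at 12 hours, 2 at 5 days, 3 for 3 days against 1 day, 92 for 5 days against 12 hours, 7 for the F-test and an overlap of 2. Centring on the median gave 2 at 5 days, 3 for 3 days against 1 day, 7 for 5 days against 3 days, 9 for the F-test and an overlap of 2. Cyclic loess gave 5 at 12 hours, 1 at 5 days, 2 for 3 days against 1 day, 6 for 5 days against 3 days, 9 for the F-test, 0 lists and an overlap of 2.

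The floor at the 1st percentile gave 0 for 3 days against 1 day. The floor at the 25th percentile gave 1 at 1 day, 1 at 5 days, 5 for 1 day against 12 hours, 5 for 5 days against 3 days, 7 for the F-test and an overlap of 0. Without a filter on dim probe sets there were 1 for the mean of the times, 27 at 12 hours, 0 for 3 days against 1 day, 98 for 5 days against 12 hours, 8 for the F-test and an overlap of 2. The filter at the 50th percentile gave 1 at 1 day, 7 for 5 days against 3 days and 7 for the F-test. The intensity trend with a robust variance gave 0 for 3 days against 1 day and 6 for 5 days against 3 days. Array weights gave 44 for the mean of the times, 491 at 12 hours, 137 at 1 day, 20 at 3 days, 7 at 5 days, 345 for 1 day against 12 hours, 103 for 3 days against 1 day, 96 for 5 days against 3 days, 483 for 5 days against 12 hours, 466 for the trend, 608 for the F-test and an overlap of 98.

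Arrays with the same number deviated together in the 1 day and 3 days groups and in no other 2 groups. In both groups array 3 alone lay in cluster 1, so arrays 1 and 2 deviate together from it in any pairing. The correlations therefore cannot tell a pairing of the numbers from the clusters. The 3 of 30 same-numbered pairs with a correlation of deviations over 0.1 were those of 1 day and 3 days, and all 30 had a range of -0.60 to 0.68 and a median of 0.0050. The replicate block in these 2 groups alone gave 0 for 3 days against 1 day, where Nalcn had 2.62 with an adjusted p of 0.0912, and changed no other call there. The replicate block over all groups gave 3 at 12 hours, 1 at 1 day, 61 at 5 days, 1 for 1 day against 12 hours, 2 for 3 days against 1 day, 24 for 5 days against 3 days, 45 for the F-test, 8 lists and an overlap of 3. In that fit only controls 1 to 3 share a number with exposed arrays. Each other control is alone in its block, is fitted exactly and adds nothing. The counts, folds and signs against control there thus rest on controls 1 to 3. Without a block, 58 probe sets were called at 5 days against controls 1 to 3. The 61 therefore cannot tell a pairing of the numbers from the choice of controls. With the replicate block over all groups the mean of the times had Vim -0.020, S100b 0.96, Slc1a2 0.14 and Apoe 0.78, 12 hours had S100b 1.11 and Slc1a3 0.035, 1 day had Vim -0.11, S100b 0.12, Glul 0.060 and Apoe 0.61, 3 days had S100b 0.18 and Slc1a3 1.00, and 5 days had Slc1a2 0.28, all of the opposite sign to the fit without it.

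Leaving out controls 1 and 2 gave 54 for the mean of the times, 321 at 12 hours, 59 at 1 day, 22 for 1 day against 12 hours, 5 for 3 days against 1 day, 18 for 5 days against 3 days, 250 for the trend, 219 for the F-test and an overlap of 49. Fits of only the groups compared gave 1 at 12 hours, 0 at 1 day, 7 for 1 day against 12 hours, 0 for 3 days against 1 day, 18 for 5 days against 3 days, 392 for 5 days against 12 hours, 236 for the trend and an overlap of 0. Camera with the correlation estimated called 0 lists, fry 7 and the mean of the probe sets of a gene 7. Of the fry calls, 6 were at 12 hours and 1 at 1 day, where camera called 0. Fry called 0 for the mean of the times, at 3 days and at 5 days, where the 4 camera calls lay. For 5 days against 3 days fry also called 0, where camera called 5.

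The block on 2 array clusters gave 3 at 12 hours, 30 at 1 day, 15 for 1 day against 12 hours, 13 for 3 days against 1 day, 0 for 5 days against 12 hours, 2 for the trend, 26 for the F-test and 9 lists, or 0 lists with the correlation estimated as well. The block on 5 array clusters gave 1 for the mean of the times, 0 at 12 hours, 1 at 1 day, 6 at 3 days, 1 for 1 day against 12 hours, 1 for 5 days against 3 days, 0 for 5 days against 12 hours, 0 for the trend and 3 for the F-test, with control 1 as the only control for 12 hours and array 3 as the only array for 1 day, each assumed to vary like the other groups. Cluster 1 alone gave 0 at 12 hours, 0 at 1 day and 1 at 3 days, where its lone arrays at 1 day and 3 days are assumed to vary like the other groups, and cluster 2 alone 123 at 1 day, 6 at 3 days, 38 for 3 days against 1 day and 0 for 5 days against 3 days, with fewer arrays in each. Without 1 day array 3 and 3 days array 3 there were 5 for the mean of the times, 30 at 12 hours, 38 at 1 day, 5 at 3 days, 44 for 1 day against 12 hours, 6 for 3 days against 1 day, 227 for the trend, 90 for the F-test and an overlap of 5.

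Leaving out 1 array at a time gave 0 to 3 for the mean of the times, 1 to 211 at 12 hours, 0 to 26 at 1 day, 0 to 3 at 3 days, 0 to 2 at 5 days, 0 to 24 for 1 day against 12 hours, 0 to 10 for 3 days against 1 day, 0 to 12 for 5 days against 3 days, 1 to 215 for 5 days against 12 hours, 11 to 225 for the trend, 1 to 114 for the F-test, 2 to 5 lists and an overlap of 0 to 5. The highest counts came without control 1 at 12 hours and in the F-test, without 1 day array 3 at 1 day, and without 3 days array 3 for the trend and for 5 days against 12 hours.

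Values of genes that passed and then reversed came from the block on 5 array clusters, where Ccl5 had -0.18 at 12 hours and 0.089 for 5 days against 12 hours, Igfbp3 had -1.47 and Lsamp -0.17 for 5 days against 12 hours, and Pcp4 had -0.076 and Foxd1 0.065 for the trend. Ccl5 for 1 day against 12 hours, which had not passed, became 0.12. The other reversed values belonged to probe sets of astrocyte genes that never passed as fitted. For Glul and Slc1a2 the reversed values, here and with the replicate block, are those of probe sets rc_AI232783_s_at and U15098_at, not of the called rc_AI012265_i_at and rc_AI044517_g_at, which never reversed. In the mean of the times, Slc1a3 had -0.012 with quantile normalization, -0.26 with array weights and -0.95 without controls 1 and 2, Apoe had 0.080 with centring, 0.10 and 0.025 with the blocks on 2 and 5 clusters, and 0.26 without 1 day array 3 and 3 days array 3, and S100b had 0.0035 with the block on 2 clusters and 0.46 without those arrays.

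At 12 hours Apoe had -0.13 with quantile normalization, -0.074 with cyclic loess, -0.36 with array weights, -0.30 without controls 1 and 2 and -0.25 with the block on 5 clusters. S100b had 0.0049 with centring, 2.54 with the block on 2 clusters and 2.07 within cluster 1, and Slc1a3 had 0.82 and 0.20 with the blocks on 2 and 5 clusters and 0.72 within cluster 1. At 1 day Slc1a3 had -0.067 with quantile normalization, -0.96 without controls 1 and 2 and -0.30 within cluster 1. Vim had -0.032 with cyclic loess, -0.068 with array weights, -0.084 with the block on 5 clusters and -0.11 without 1 day array 3 and 3 days array 3. Apoe had 0.11 with array weights, 0.33 within cluster 2 and 0.64 without those 2 arrays, and S100b had 0.10 with the block on 5 clusters and 0.39 without them. Glul had 0.28 with the block on 5 clusters, 0.015 within cluster 2 and 0.012 without those arrays, and Slc1a2 on U15098_at had -0.24 with the block on 5 clusters and -0.45 within cluster 1.

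At 3 days Vim had 0.033 with quantile normalization, 0.090 without controls 1 and 2 and 0.029 within cluster 2. With the block on 5 clusters Glul had 0.034, Slc1a2 0.21, Slc1a3 0.44 and Apoe 0.13, and without 1 day array 3 and 3 days array 3 S100b had 0.53 and Slc1a3 0.73. At 5 days Slc1a2 had 0.052 with quantile normalization, 0.027 with centring and 0.13 with cyclic loess, S100b had -0.23 and -0.16 with the blocks on 2 and 5 clusters, and Glul had -0.012 with the block on 5 clusters.

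With 1 array left out at a time, Apoe ranged from -0.31 to 0.20 in the mean of the times, -0.29 to 0.22 at 12 hours and -0.62 to 0.64 at 1 day. S100b ranged from -1.23 to 0.073, -1.08 to 0.11, -2.07 to 0.39 and -2.02 to 0.53 in the mean of the times and at 12 hours, 1 day and 3 days. Slc1a3 ranged from -0.47 to 0.32 in the mean, -0.55 to 1.18 at 1 day and -0.80 to 0.73 at 3 days. Vim ranged from -0.041 to 0.18 in the mean, -0.14 to 0.13 at 1 day and -0.16 to 0.062 at 3 days. Glul ranged from -0.048 to 0.16 in the mean and -0.23 to 0.012 at 1 day, and Slc1a2 from -0.10 to 0.37 at 1 day and -0.27 to 0.040 at 5 days.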

Other observations

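The test of the markers named here was chosen only after results were seen. Of the other cell type markers measured, 1 of 15 neuron markers, Map2, was lower in cluster 1 without overlap, 0 of 6 oligodendrocyte lineage markers had separate ranges, and 1 of 4 fibroblast, meningeal and vascular markers, Igf2, was higher in cluster 1. A single microglia and macrophage marker, Itgam, was measured.

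In the tree divided into 5 clusters, controls 1, 2 and 3 each lay with exposed arrays of other times than controls 4 to 6 did, and 1 day arrays 1 and 2 lay apart without a control. The 5 clusters took 74.6% of the sum of squares with 4 degrees of freedom, against 39.6% for the 5 groups. A candidate explanation is that single controls were prepared together with particular exposure times, in which case a fold against all 6 controls mixes peptide with preparation. The labels do not say so, and no test here can decide it. With the block on 5 array clusters limma called 0 probe sets at 12 hours, 1 at 1 day, 6 at 3 days and 0 between 5 days and 12 hours. That fit compares 12 hours with control 1 alone and 1 day through array 3 alone, each assumed to vary like the other groups, so its counts decide nothing here.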
